A study of Ovis aries with 30 samples.

How the data were processed

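Whole liver tissue of 30 lambs was profiled, 15 from control and 15 from biosolids-exposed ewes. Per the labels' protocols, RNA was isolated from frozen liver with a column kit, libraries were made with a TruSeq RNA kit and sequenced on a NovaSeq S4 flow cell. Per the submitters' processing notes, the tools were Trimmomatic, FastQC, MultiQC, STAR and featureCounts 1.5.0-p3; the notes give no roles or settings, and whether counting used strand is not given in the sources used here, so overlapping and antisense genes were not told apart. The unit is whole-number gene counts as deposited, not normalized, in 1 table of the series with a column per lamb, of which 0 columns were left without a lamb. Groups were taken from the labels for exposure and sex, and each lamb is named by its tag number. No batch is labelled, and tag numbers of control and exposed lambs do not overlap, so flock or processing day cannot be told apart from exposure. Litters are not labelled either. The tests took each lamb as independent, so p-values for exposure could be too small where lambs shared a dam. Groups share no replicate numbers.

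The table held 31304 gene rows. 7 genes with long exon lists (among them NEB and HUWE1) were broken over 25 lines, and their pieces were joined before use. 28862 genes matched the RefSeq table of assembly ARS-UI_Ramb_v3.0 by symbol, and the start and end were identical in all 28855 that could be compared, so coordinates are given in that assembly, counted from 1. Genes with near-identical copies, ribosomal RNA rows included, are uncertain where reads could be split between copies.

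Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups (17840 genes), libraries were scaled by TMM, and 1 model with a mean for each of the 4 groups was fitted by the robust quasi-likelihood method with 26 residual degrees of freedom. The biological coefficient of variation was 35.2%. Contrasts were exposure within females, within males and averaged over both, the interaction (the effect in males minus that in females), and males against females within controls and within exposed lambs. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the fold change and the F statistic. CPM values use the TMM-scaled library sizes. P-values measure the spread between lambs.

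Of 45 gene lists of liver functions and cell types, 43 had at least 5 tested members. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. After the data were seen, the mean log2 CPM of a list per lamb (prior count 2) was added and compared by exact two-sided permutation of exposure within sex (12870 splits of 8 against 8 and 3432 of 7 against 7), by 100000 resamples for both sexes and the interaction, and by exact permutation of sex within exposure. List means were also compared with single lambs left out and, for sex in controls, with the mean of the ribosomal protein list as a term in the 4-group model. Within-group spread was tested by exact permutation, as the median absolute deviation over genes scaled to a standard deviation.

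The lists, tests and rule for naming genes were fixed before the data were examined. The rule took, for exposure and for sex in controls, the 10 higher and 10 lower called genes with a symbol and at least 1 CPM that changed most, or the 5 smallest p in each direction where fewer than 5 passed; the 5 smallest p in each direction of the interaction; of each list described, at most 8 members that passed or otherwise the 2 with the smallest p; and a fixed set of metabolic and receptor genes, some of which are not reported here. Genes called without a symbol, genes called in exposed lambs by sex, by DESeq2, and LOC101112291 in the check of sex labels were named after their values were seen.

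Alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, at least 1 CPM in 15 libraries, 2 surrogate variables from sva 3.50.0, limma voom with sample quality weights, a fold-change limit of 0.5 on the log2 scale, an adjusted p of 0.1, fits within 1 sex, additive and sex-free models, and leaving out each lamb in turn. After the data were seen, fits without biosolids male 8778 and control female 8263 were added. The tests were checked on counts simulated from the means and library sizes of these lambs, with 100 genes changed by 1 and 100 by 2 log2 units. The changed genes were drawn from those with a mean of at least 1 CPM, the proteasome list was shifted as well, and genes varied independently of each other. The shares recovered therefore do not cover weaker genes, a case with few changed genes or variation shared between genes. For each model result, 100 splits of the lambs, the real one included, were refitted, with exposure exchanged within sex or sex within exposure. Python with scipy was used for permutation tests and matplotlib for figures. Shares of counts carry 95% Wilson intervals, which cover counting error only.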

Results

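Liver RNA was sequenced from 30 lambs of the first generation born to ewes that had been kept, before conception and through pregnancy, on pasture treated with biosolids or on control pasture. Biosolids are processed sewage sludge spread as fertiliser and carry a mixture of environmental chemicals at low levels. There were 8 control females, 7 control males, 8 biosolids females and 7 biosolids males, and each library came from its own animal tag. Total counts per library lay between 18.7 and 51.9 M (mega-counts). They ranged from 29.8 to 39.1 M in control females, from 32.7 to 51.9 M in control males, from 24.1 to 42.8 M in biosolids females and from 18.7 to 43.3 M in biosolids males. In the library of biosolids male 8778, 87.5% of the counts fell on ribosomal RNA rows (95% Wilson interval 87.49 to 87.52%, counting error only), against 0.299 to 7.69% in the other 29 libraries, which left 2.34 M counts for all other genes. Among the other libraries, that of control female 8263 was the least like the rest, with a median Spearman correlation with the others of 0.943, where the next lowest was 0.957.

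**Figure D1:**
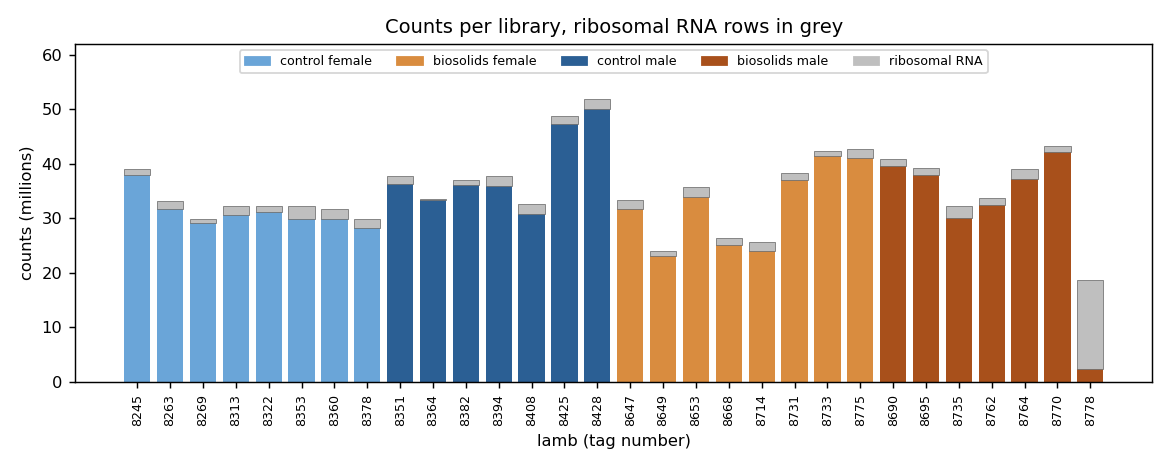
Counts per library in units of M (vertical axis) for each lamb by tag number (horizontal axis), coloured by group, with counts on ribosomal RNA rows stacked in grey. The grey part fills most of the bar of biosolids male 8778, at 87.5% of its counts, and at most 7.69% of any other bar.

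The sex labels were checked on rows of the Y chromosome. Rows were chosen under the labels as those whose lowest level in males lay well above the highest in females. 7 Y-linked rows met this, so that they separated the 14 males from the 16 females without overlap by choice. What bears on the labels is that rows with such a gap exist. Among them, LOC132659055 (chromosome Y, 7386786 to 7527683 in assembly ARS-UI_Ramb_v3.0) lay between 19.2 and 42.0 CPM in males and at no more than 0.0294 CPM in females, and LOC132659062 (chromosome Y, 8508157 to 8553310) lay between 12.5 and 45.0 CPM in males and at no more than 0.0432 CPM in females, with ribosomal RNA left out of the library sizes. The opposite pattern was seen for LOC101112291, a long non-coding RNA of the X chromosome (66054191 to 66091351), which lay between 318 and 824 CPM in the females and at no more than 2.05 CPM in 13 of the males. Control male 8408 was the exception, with 302 CPM of LOC101112291 beside Y-linked rows whose median was 75.4% of that of the other males, who ranged from 76.2 to 176%.

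The first comparison asked whether exposure changed the liver transcriptome of female lambs. The 5 genes with the smallest p among those higher in exposed females were FCGBP, TFF3, ERN2, TSPAN1 and TMC5, none of which passed the test. FCGBP and TFF3 encode secreted partners of mucus in mucous epithelia. FCGBP stood at 50.7 ± 104 CPM in exposed and 2.69 ± 1.03 CPM in control females (SD, n = 8 each), a log2 fold change of 4.23 ± 0.96 (SE) with an adjusted p of 0.95 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 2 exposed females 8649 and 8668 held 299 and 84.6 CPM of FCGBP, while the median of the group was 4.27 CPM. TFF3 likewise reached 310 CPM in lamb 8649 and 33.5 CPM in lamb 8668, with a group median of 1.01 CPM. On the lower side the 5 genes were UPK3B, LOC105604571, TBCEL, LOC114113172 and LOC114116874, again without passing. TBCEL averaged 35.5 ± 9.33 CPM in exposed and 58.6 ± 20.7 CPM in control females (SD, n = 8 each), and UPK3B, a uroplakin that also marks mesothelium, 0.22 ± 0.191 against 1.39 ± 1.54 CPM.

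No gene of 17840 passed an adjusted p of 0.05 in females by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 652 genes, where chance alone gives 892, and neither DESeq2 nor limma voom with sample weights called any. In counts simulated from these libraries, the same test recovered 69 of 100 genes changed by 1 log2 unit and 96 of 100 changed by 2 in this comparison, over 17687 genes. The changed genes had a mean of at least 1 CPM and varied independently. These shares thus do not give the recovery of weaker genes or under variation shared between genes.

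Among the gene lists fixed beforehand, the interferon-stimulated genes stood out in females by size. All 32 measured members had a lower mean in exposed females, with a median log2 fold change of -1.32, and 17 passed when adjusted over the list alone against 0 over all genes. ISG20, at -4.19 ± 1.17 (SE), and IFIT3, at -3.13 ± 0.91, had the smallest p of the list. Control female 8263 set this difference: its mean log2 CPM over the list was 8.06, the next highest control female had 6.34, and the group medians were 4.44 in controls and 4.51 in exposed lambs. The exact two-sided permutation test of the list mean per lamb gave a difference of -0.46 log2 units (p = 0.492, adjusted p = 0.977), and -0.01 without lamb 8263 or -0.26 without control female 8378. Lamb 8263 also had the highest means of all lambs for antigen presentation, macrophage markers and T and NK cell markers, at 7.63, 6.36 and 3.31 log2 CPM. Markers of hepatic stellate cells and fibroblasts had a higher mean in exposed females for 19 of 21 members, led by FBLN1 at 1.40 ± 0.40, the only member to pass when adjusted over the list alone, and COL1A2 at 0.72 ± 0.31. FBLN1 stood at 12.9 and 11.1 CPM in lambs 8649 and 8668, the lambs with most FCGBP, where the group median was 2.61 CPM. These lambs also had the highest list means of the females, 4.61 and 4.59 log2 CPM. Without both, the difference of the list means was 0.09 in place of 0.28. They led the cholangiocyte markers as well, at 4.44 and 3.26 log2 CPM. That list had a higher mean in exposed females for 8 of 12 members, with CLDN7 at 1.98 ± 0.64, the only member to pass when adjusted over the list alone. Its difference of 0.16 became -0.08 without lamb 8649, 0.09 without lamb 8668 and -0.20 without both. It was 0.10 without control female 8313 and 0.09 without control female 8378. The cholesterol synthesis and uptake list had a lower mean for 21 of 23, led by FDPS at -0.86 ± 0.33 and NSDHL at -0.52 ± 0.23, and control female 8378 held 17.2 CPM of FDPS where the median of controls was 3.02 CPM. The difference of the list means was -0.20 with that lamb, whose list mean was 6.36 log2 CPM, and -0.06 without it. Exposed female 8668, the highest of its group at 5.84 log2 CPM, pulled the difference the other way, so it is not set by lamb 8378 alone. With camera's preset correlation of 0.01, 10 of 43 lists passed in females, 6 higher and 4 lower, among them the interferon, stellate cell, cholangiocyte and cholesterol lists. None passed with an estimated correlation (smallest adjusted p = 0.885; 0.928 for the interferon, cholangiocyte and cholesterol lists and 0.885 for the stellate cell list), by fry or by the permutation test, and without control female 8263 the preset called 5.

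The same question was asked in males. LCN2, the iron-scavenging lipocalin of the acute phase (chromosome 3, 8108566 to 8128289), had the smallest p among genes lower in exposed males. It averaged 25.3 ± 10.8 CPM in control males and 9.53 ± 4.04 CPM in exposed males (SD, n = 7 each), a log2 fold change of -1.41 ± 0.29 (SE) with an adjusted p of 0.144 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In females LCN2 stood at 9.37 ± 3.15 CPM in controls and 9.58 ± 3.80 CPM in exposed lambs (n = 8 each), so that control males were the group that differed. MUC1, a membrane mucin, showed the same layout, with 18.8 ± 2.61 CPM in control males and 9.48 ± 3.77 CPM in exposed males, against 10.1 ± 3.40 and 9.94 ± 2.61 CPM in control and exposed females. TEAD4, a transcription factor of the Hippo pathway, stood at 17.8 ± 2.76 CPM in exposed and 28.8 ± 7.58 CPM in control males. The other genes of the lower side were LOC114108606, at -4.66 ± 0.99, and LOC101112291, whose log2 fold change of -7.52 ± 1.60 rests on control male 8408. On the higher side the 5 smallest p belonged to the ribosomal RNA rows KEF53_r02, LOC121818848, LOC114112702 and LOC121818850 and to LOC121818987, all of them set by biosolids male 8778, which held 14600 CPM of KEF53_r02 where the group median was 10.1 CPM.

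No gene passed in males by edgeR's quasi-likelihood test, with 970 at an unadjusted p under 0.05 where chance gives 892. limma voom with sample weights called 0, and DESeq2 called 4: LOC101112291, LOC114108606, LCN2 (log2 fold change -1.40 ± 0.29, adjusted p = 0.00828) and LOC101105149. In the simulated counts for males, 66 of 100 genes changed by 1 log2 unit and 93 of 100 changed by 2 were recovered, over 17687 genes.

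**Figure D2:**
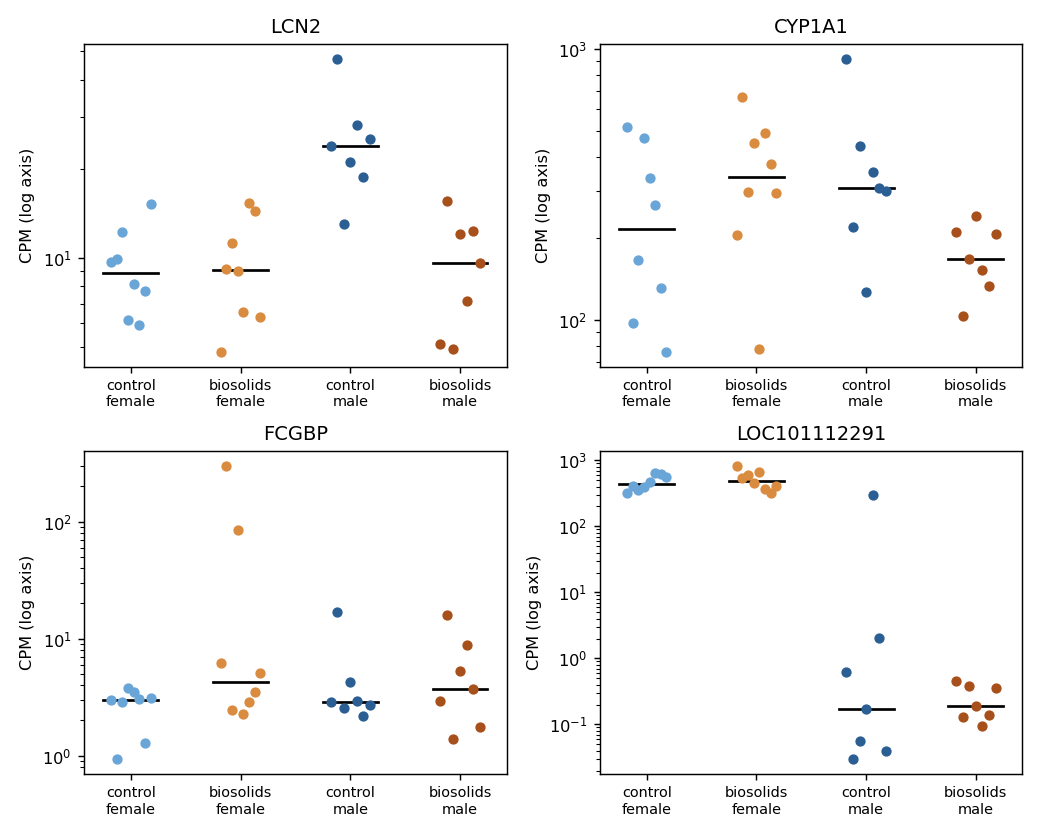
CPM on a log axis for LCN2, CYP1A1, FCGBP and LOC101112291 in each lamb (points) of the 4 groups, with the group median as a bar. Control males lie highest for LCN2, exposed females 8649 and 8668 lie apart for FCGBP at 299 and 84.6 CPM, and control male 8408 lies at the level of females for LOC101112291 at 302 CPM.

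The acute phase list, liver proteins whose synthesis follows inflammatory signals, had a lower mean in exposed males for 19 of 20 members, with a median log2 fold change of -0.42. IL1RN, at -0.59 ± 0.14 (SE), and LBP, at -1.04 ± 0.35, had the smallest p, and IL1RN alone passed when adjusted over the list alone, against 0 over all genes. The mean log2 CPM of the list was 9.95 ± 0.24 in control males and 9.43 ± 0.37 in exposed males (SD, n = 7 each), and the exact two-sided permutation test gave p = 0.00758, which did not pass over the 43 lists (adjusted p = 0.242). The immediate early genes had a lower mean for 23 of 24 members, with a median of -0.42, led by FOS at -1.54 ± 0.47 and JUNB at -0.60 ± 0.21 (exact permutation p = 0.0134, adjusted p = 0.242). A metabolic list, gluconeogenesis and amino acid use, ranked next by this test, with list means that differed by -0.21 (exact permutation p = 0.0169, adjusted p = 0.242). Complement and coagulation genes were lower on average for 29 of 30 members, led by MASP2 at -0.34 ± 0.15 and C5 at -0.65 ± 0.30. The cytosolic ribosomal proteins were higher on average for 70 of 74, led by RPL30 at 0.66 ± 0.22 and RPS27A at 1.49 ± 0.53, and the nuclear genes of oxidative phosphorylation for 53 of 59, led by NDUFB3 at 1.09 ± 0.36 and ATP5PD at 0.68 ± 0.26. Hepatocyte markers, of which FGB is also in the acute phase list, were lower on average for 14 of 15, with AHSG at -0.39 ± 0.22 and ASGR2 at -0.29 ± 0.19, and their list mean differed by -0.18 (exact permutation p = 0.0752, adjusted p = 0.539). RPS27A and NDUFB3 were highest in the library of biosolids male 8778, at 248 and 22.4 CPM against group medians of 23.4 and 4.61 CPM. Without that library the difference of the list means was 0.14 in place of 0.29 for the ribosomal proteins, which was 0.16 without biosolids male 8735, and 0.11 in place of 0.23 for oxidative phosphorylation. The immediate early list mean was lowest of all lambs in the library of 8778, at 3.125 log2 CPM. Without that library this list differed by -0.34 in place of -0.43 (exact permutation p = 0.0321, adjusted p = 0.481). The acute phase list then differed by -0.54 in place of -0.52, and gluconeogenesis and amino acid use by -0.18 in place of -0.21. With camera's preset correlation 14 of 43 lists passed in males, 3 higher and 11 lower. None passed with an estimated correlation (adjusted p = 0.148 for immediate early genes, 0.229 for acute phase genes and 0.655 for the complement, ribosomal protein, oxidative phosphorylation and hepatocyte marker lists), by fry or by the permutation test, and the preset called 7 without biosolids male 8735 and 8 without biosolids male 8778.

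**Figure D3:**
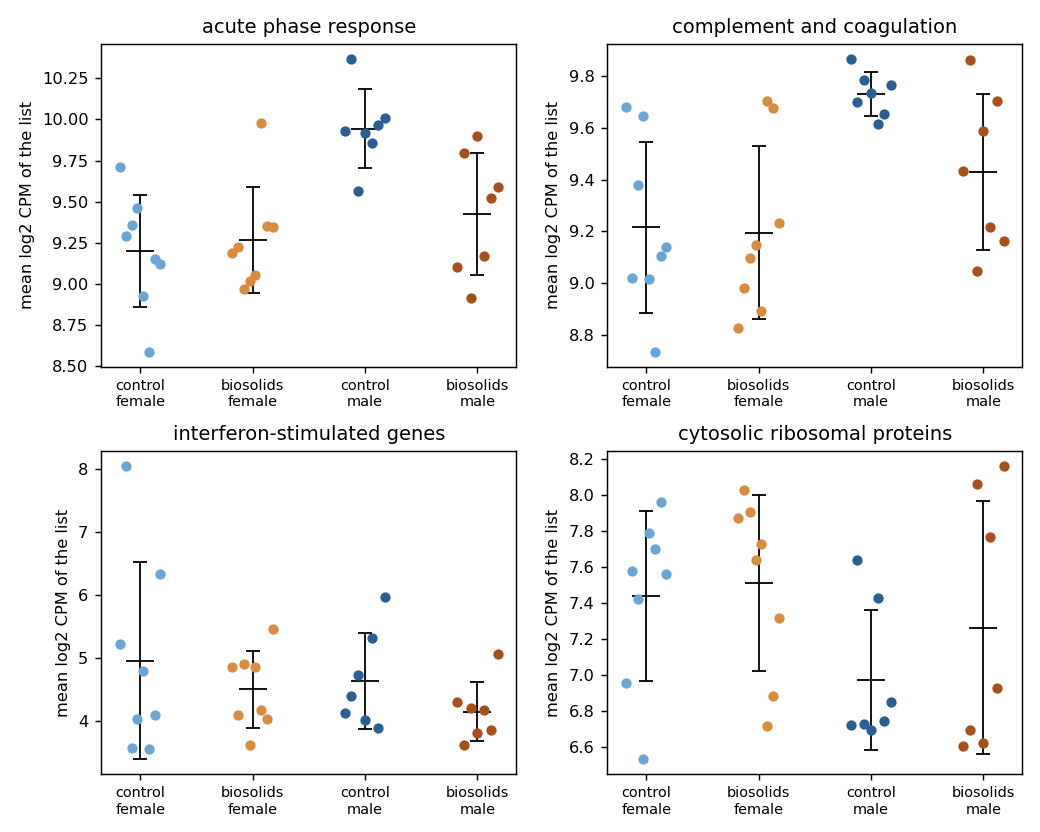
Mean log2 CPM of the members of 4 gene lists in each lamb (points), with the mean and SD of each group as bars. Control males lie highest for the acute phase list, at 9.95 against 9.43 in exposed males, and control female 8263 lies apart for the interferon list at 8.06.

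Over both sexes, the genes with the smallest p on the lower side were LOC114108606, LOC101118112, TEAD4, FCRL6 and LOC101112291. LOC101118112 (chromosome 9, 15429193 to 15486365), a protein-coding gene without a symbol, averaged 16.5 ± 3.61 CPM in exposed and 23.8 ± 5.06 CPM in control females (n = 8 each), and 21.2 ± 7.59 against 35.7 ± 9.47 CPM in males (SD, n = 7 each). Its log2 fold change was -0.63 ± 0.13 (SE) with an adjusted p of 0.469 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and LOC114108606, at -3.30 ± 0.63, had the smallest adjusted p of 0.21. The higher side held the ribosomal RNA rows KEF53_r02, LOC121818848, LOC114112702 and LOC121818850, set by lamb 8778, and LOC114109243 at 0.70 ± 0.17. No gene passed by edgeR's quasi-likelihood test, with 768 at an unadjusted p under 0.05. limma voom with sample weights called 0 and DESeq2 called 4, LOC114108606, LOC132657222, LOC101112291 and LOC101118112. For LOC101112291 the male part of this difference rests on control male 8408, at 302 CPM where every other male had at most 2.05 CPM. In the simulated counts for both sexes, 85 of 100 genes changed by 1 log2 unit were recovered, over 17687 genes. With the preset correlation 13 of 43 lists passed, 4 higher and 9 lower, and none passed with an estimated correlation (smallest adjusted p = 0.603), by fry or by the permutation test of the list means.

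Genes named beforehand for chemical exposure and metabolism showed no change that passed. CYP1A1, the monooxygenase induced through the aryl hydrocarbon receptor, stood at 356 ± 181 CPM in exposed and 257 ± 169 CPM in control females, a log2 fold change of 0.47 ± 0.39 (SE), and at 174 ± 48.6 against 381 ± 258 CPM in males, a log2 fold change of -1.13 ± 0.43 with an adjusted p of 0.816 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 10 measured aryl hydrocarbon receptor targets, 7 had a lower mean in exposed males and 7 in exposed females, and the list did not pass in either sex. Its mean differed by -0.31 in males (exact permutation p = 0.0455, adjusted p = 0.391) and by -0.01 in females (exact permutation p = 0.945, adjusted p = 0.977). FGF21, a hormone of fasting, had log2 fold changes of 0.83 ± 0.77 in females and 1.71 ± 0.84 in males, with 71.8 CPM in 1 exposed male and a group median of 5.33 CPM. SREBF1, FASN and SCD, which serve fatty acid synthesis, were at -0.43 ± 0.28, -0.20 ± 0.14 and -0.67 ± 0.36 in females and at -0.37 ± 0.30, -0.22 ± 0.15 and 0.07 ± 0.39 in males. CPT1A, PPARA, PCK1, G6PC1, IGF1, IGF2, IGFBP1 and ESR1 lay between -0.43 and 0.27 in both sexes, all without passing. CYP1A2, CYP1B1, CYP7A1 and MT2A were not analysed here.

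The interaction compared the effect in males with that in females. The smallest p among genes with the lower effect in males belonged to FBLIM1, LOC101112291, IL1RN, DPM2 and WNT2B. IL1RN, the interleukin 1 receptor antagonist, stood at 88.0 ± 15.4 CPM in control and 58.4 ± 9.27 CPM in exposed males (SD, n = 7 each), and at 73.6 ± 17.0 and 84.0 ± 14.7 CPM in females (n = 8 each). FBLIM1, a filamin-binding adaptor, stood at 8.02 ± 1.98 and 5.50 ± 1.08 CPM in control and exposed males and at 5.65 ± 1.79 and 9.51 ± 3.45 CPM in females. Neither passed, with interaction terms of -0.78 ± 0.20 and -1.30 ± 0.30 log2 units (SE) and adjusted p of 0.684 and 0.553 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. On the other side stood the ribosomal RNA rows LOC121818848, LOC114112702 and KEF53_r02, then GSDME and LOC101105149. GSDME, a pore-forming gasdermin, was at 122 CPM in control female 8360 and at 127 CPM in biosolids male 8735, where all other lambs had at most 2.48 CPM. No gene passed by edgeR's quasi-likelihood test, with 648 at an unadjusted p under 0.05, 0 by limma voom with sample weights and 1 by DESeq2, LOC101112291. The effect in males for LOC101112291 rests on control male 8408, at 302 CPM where every other male had at most 2.05 CPM. For the acute phase list the interaction of the list means was -0.58 log2 units (permutation p = 0.027, adjusted p = 0.596). It was -0.44 for the immediate early genes and -0.29 for gluconeogenesis and amino acid use (permutation p = 0.0394 and 0.0415, adjusted p = 0.596 for both). Across genes, which are not independent replicates, the effects of exposure in females and in males had a Pearson correlation of 0.0422 and a Spearman correlation of 0.017.

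Among controls, males differed from females in 15 genes, 11 higher and 4 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. 9 of them were Y-linked and 3 were X-linked genes higher in females: ZFX at 49.6 ± 9.07 CPM in females (SD, n = 8) and 29.1 ± 6.66 CPM in males (n = 7), EIF2S3 at 76.8 ± 16.7 and 44.6 ± 13.6 CPM, and KDM6A at 33.0 ± 3.28 and 21.0 ± 2.78 CPM. LCN2 was higher in control males, with a log2 fold change of 1.43 ± 0.28 (SE, adjusted p = 0.0216), as was NCAM1, a neural cell adhesion molecule, at 2.07 ± 2.02 against 0.11 ± 0.0824 CPM (4.17 ± 0.82, adjusted p = 0.0261). The same 7 control males enter the exposure effect in males and the interaction. Differences of LCN2 and the acute phase genes in those comparisons and in this one are therefore not independent of each other. LOC132657733, a non-coding RNA of chromosome 14, was lower in control males at 4.20 ± 0.475 against 9.57 ± 3.57 CPM. The acute phase list was higher in control males for all 20 members, with a median of 0.66, and 14 passed when adjusted over the list alone against 0 over all genes. STEAP4, a metalloreductase, at 1.23 ± 0.35 and LBP, the lipopolysaccharide-binding protein, at 1.13 ± 0.34 had the smallest p of the list, to which LCN2 does not belong. Complement and coagulation genes were higher on average for all 30 members, with a median of 0.48, and 18 passed when adjusted over the list alone against 0 over all genes, with C9 at 0.63 ± 0.19 and MASP1 at 0.70 ± 0.21. In exact two-sided permutation tests of the list means, chosen after the data were seen, the acute phase list was 0.74 log2 units higher in control males (adjusted p = 0.0267 over 43 lists), complement and coagulation 0.52 (adjusted p = 0.0334) and the stellate cell and fibroblast markers, with COL3A1 at 0.98 ± 0.26 and COL1A2 at 1.14 ± 0.32, 0.46 (adjusted p = 0.0334). Of these, fry called the acute phase list (adjusted p = 0.00995) and the complement list (adjusted p = 0.0486), while camera with an estimated correlation gave adjusted p of 0.323, 0.511 and 0.511. Hepatocyte markers were higher on average in control males for 12 of 15, without passing, with a difference of 0.28 log2 units (exact permutation p = 0.0277, adjusted p = 0.149), with AHSG at 0.50 ± 0.21 and TF at 0.51 ± 0.23. Other list means were lower in control males without passing. The difference was -0.46 for cytosolic ribosomal proteins (exact permutation p = 0.062, adjusted p = 0.234). It was -0.38 for nuclear oxidative phosphorylation genes and -0.25 for the proteasome (exact permutation p = 0.0143 and 0.0214, adjusted p = 0.102 and 0.132). A term for the mean ribosomal protein level of each lamb was added after the data were seen. It left 82.2% of the acute phase difference, 59.9% of the complement difference, 94.5% of the stellate cell difference and 43.4% of the hepatocyte marker difference (jackknife SE 16, 17, 20 and 19%). A share of library composition in these differences is therefore not excluded. At an unadjusted p under 0.05 there were 3370 genes in this comparison, DESeq2 called 54 and limma voom with sample weights 64, and edgeR called 23 without control female 8245.

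Outside chromosome Y, only ZFX of these calls passed in all 30 edgeR fits with 1 lamb left out. LCN2 passed in 24 and missed the threshold without control females 8313, 8322, 8353 and 8360 and control males 8364 and 8428 (adjusted p from 0.0507 to 0.0787). NCAM1 passed in 20 and missed it without control females 8263, 8269, 8313, 8322, 8353, 8360 and 8378 and control males 8364, 8382 and 8425 (adjusted p from 0.0579 to 0.111). EIF2S3 passed in 22, KDM6A in 22 and LOC132657733 in 18, with adjusted p of at most 0.0907, 0.0866 and 0.105. LOC132657733 missed it without control females 8263, 8269, 8353, 8360 and 8378 and each control male. EIF2S3 missed it without control females 8322, 8353 and 8360 and control males 8351, 8382, 8394, 8425 and 8428. KDM6A missed it without control females 8313 and 8360 and control males 8351, 8364, 8382, 8394, 8425 and 8428. LCN2 and NCAM1 were also lost with 2 surrogate variables (adjusted p = 0.148 for both) and without biosolids male 8778 and control female 8263 (0.0519 and 0.0811), and NCAM1 with limma voom (0.0696), at log2 fold changes of 1.29 and 4.24, 1.44 and 4.18, and 3.80. EIF2S3 and LOC132657733 were lost with 2 surrogate variables as well (adjusted p = 0.195 and 0.541), as their log2 fold changes shrank from -0.78 ± 0.15 to -0.55 ± 0.13 and from -1.19 ± 0.24 to -0.81 ± 0.22 (SE). With 2 surrogate variables and both libraries left out, EIF2S3 passed (-0.60 ± 0.10, adjusted p = 0.00467), while LOC132657733 (0.136), LCN2 (0.186) and NCAM1 (0.189) did not.

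In exposed lambs, males differed from females in 17 genes, 15 higher and 2 lower. 9 were Y-linked, and 10 genes, these 9 and KDM6A, were called in both sex comparisons. LOC101112291 was at 521 ± 169 CPM in exposed females (SD, n = 8) and 0.25 ± 0.143 CPM in exposed males (n = 7). The other 6 calls were the 5 ribosomal RNA rows LOC121818850, LOC121818848, LOC114112489, LOC114112702 and KEF53_r02 and the non-coding RNA LOC121818987, again from biosolids male 8778; with that library and control female 8263 left out, a choice made after the data were seen, 14 genes passed. Without lamb 8778 alone, the adjusted p of the 6 lay between 0.733 and 0.924, and DESeq2, limma voom and 2 surrogate variables did not call them either, while KDM6A and LOC101112291 passed in all 30 fits with 1 lamb left out. At an unadjusted p under 0.05 there were 865 genes. The acute phase list means were 9.27 ± 0.32 in exposed females and 9.43 ± 0.37 in exposed males. In exact permutation tests, exposed males exceeded exposed females by 0.16 log2 units for this list (adjusted p = 0.806). The difference was 0.235 for complement and coagulation (adjusted p = 0.806) and 0.0175 for stellate cell and fibroblast markers (adjusted p = 0.941). By this test these lists thus passed in controls only. Whether the sex difference changed is tested by the interaction, where no list passed by permutation (smallest adjusted p = 0.596).

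Within-group spread was taken as the median absolute deviation of a library's log2 CPM from its group means. It was 0.365 ± 0.068 in exposed and 0.418 ± 0.0735 in control females (SD, n = 8 each; exact two-sided permutation p = 0.151), and 0.439 ± 0.12 in exposed and 0.335 ± 0.094 in control males (n = 7 each; exact permutation p = 0.0915). Without biosolids male 8778 the difference in males was 0.0376 in place of 0.104 (exact permutation p = 0.434).

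**Figure D4:**
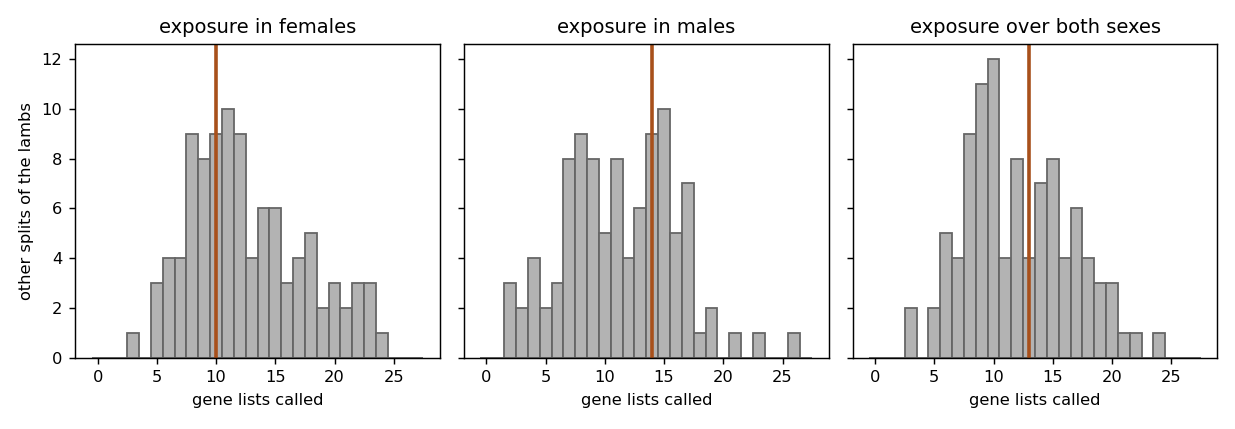
Number of gene lists called with the preset correlation (horizontal axis) in 99 other splits of the lambs by exposure within sex (grey bars, number of splits on the vertical axis), for females, males and both sexes, with the real split as a line. The real splits lie at 10, 14 and 13 lists, inside the range of the other splits, which reached 24, 26 and 24.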

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

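The extra-X test, the macrophage and neutrophil test and the margins for spread around the bounds of the epithelium, X-linked RNA and composition tests were chosen after the results were seen; the other tests were written down first. Each library was compared with the rest of its group for 63 reported measures, and a lamb was singled out where its gap to the nearest other lamb took most of the group's range. This singled out 25 values in 252 groups of values, where chance would give about 13 for independent measures not chosen from the data. Many of the measures were genes named for a small p in these data, and the ribosomal RNA rows repeat the signal of lamb 8778. The excess over 13 therefore cannot show more outliers than chance gives. Biosolids male 8778 accounts for 11 of the 25. Its ribosomal RNA share was 87.5% of counts, and its log2 CPM was 13.8 for KEF53_r02, 19.4 for LOC121818848, 14.9 for LOC114112702, 18.7 for LOC121818850, 20.3 for LOC114112489 and 9.79 for LOC121818987, each the highest of its group. It was lowest of its group for the stellate cell and fibroblast markers (mean log2 CPM 3.10), LOC114116874 (-4.20), KDM6A (3.04) and IGF2 (10.3). Control male 8364 was lowest for LOC121818848 (6.42) and LOC121818850 (6.74) and highest for FCGBP (4.09).

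The other lambs that stood apart are given as values on the same log2 CPM scale. Control female 8245 had the highest total of its group, 39.1 M counts. Control female 8263 was highest for IL1RN (6.84) and lowest for IGF2 (10.5). Control female 8378 was highest for the cholesterol list (mean 6.36), and biosolids female 8731 for the acute phase list (mean 9.98). ERN2 was highest in biosolids male 8695 (1.08), UPK3B in biosolids male 8770 (0.90) and LOC105604571 in control male 8408 (2.95). GSDME reached 6.94 in control female 8360 and 6.99 in biosolids male 8735.

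Control male 8408 also had 8.24 log2 CPM of LOC101112291, where the median of its group was -2.16. Its level was 65.4% of the median of females. If RNA of a female had been mixed in at that share, in the tube or from cells of a female twin in the liver, Y-linked rows would lie near 34.6% of the other males; their median lay at 75.4%, just under the range of 76.2 to 176% in the other 13 males. The mean of ZFX, KDM6A and EIF2S3 stood at 69.6% of the way from the other males to females. This lay above the highest other male (46.3%) and above the lowest female (61.4%), as an extra X chromosome could also give. By gene, KDM6A and EIF2S3 lay above every other male, while ZFX at 40.6 CPM lay under biosolids male 8735 at 41.8 CPM. Mixed RNA, cells of a twin and an extra X cannot be told apart here, because the level of LOC101112291 varies between females and the Y-linked rows sit at the edge of the male range.

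The acute phase genes that were lower in exposed than in control males may reflect the exposure, the composition of the libraries, a single lamb or fewer immune cells. With the mean level of ribosomal proteins as a term, 84.0% of the difference was left (-0.43 in place of -0.52 log2 units; jackknife SE 24.7%), and with any 1 of the 14 males left out at least 83.5% was left, which argues against both as the whole cause. Macrophage markers differed by 0.0497 log2 units in males (exact permutation p = 0.794). Neutrophil markers, with 7 tested members, differed by -0.19 (exact permutation p = 0.399). Neither difference stood out from the spread between lambs, so a change in immune cells stays open. Hepatocyte markers differed in the direction of the acute phase genes, by -0.18 (exact permutation p = 0.0752), so that a change in hepatocytes as a whole stays open too. Chance stays open too, since the difference did not pass over the 43 lists, and the biological effect of exposure is untested beyond that.

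The mucous epithelium genes with the smallest p in exposed females may come from gallbladder or large-duct epithelium in the pieces of a few lambs. Over the 16 females, the mean of FCGBP, ERN2, TFF3, TSPAN1 and TMC5 had a Spearman correlation of 0.171 (permutation p = 0.52) with the mean of 9 other epithelial markers, under the bound of 0.2 set against this explanation, but by less than the 0.258 by which such a value varies with no relation. Leaving out lambs 8649 and 8668 it was -0.24. Lambs 8649 and 8668 nevertheless had the highest means of these markers, 4.31 and 3.28 log2 CPM against at most 1.90 in the other 14, and in each 6 of the 9 exceeded 3 times the median of the other 14, among them KRT19 at 47.9 and 17.9 against 3.79 CPM and EPCAM at 23.4 and 4.01 against 1.16 CPM, while CLDN4 was at 86.3 and 130 against 124 CPM; the cholangiocyte list, which shares KRT19, EPCAM and CLDN4, was highest in both as well. MUC5B was at 0.397 CPM in lamb 8649, under the median of 0.698 CPM in the other 14, and at 2.37 CPM in lamb 8668. TFF2 was at 28.3 CPM in lamb 8649 and 51.0 CPM in lamb 8668. Ranks over 16 lambs weigh mainly the 14 without the signal, in which CLDN4, TFF2 (29.3 CPM) and MUC5AC (24.3 CPM) were expressed as well. The explanation therefore stays open, with most but not all of these markers in both lambs on its side.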

How the results depend on the processing

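The counts of 0 genes for exposure in females held under every setting run, while DESeq2 called 4 in males, 4 over both sexes and 1 for the interaction; the other settings gave 0 there. For sex in controls (15 genes), at least 1 CPM in 15 libraries gave 3 and for sex in exposed lambs (17 genes) it gave 7, as that filter left 9 of the calls untested in each, mostly Y-linked genes; in controls 3 more were tested and lost (LCN2 and EIF2S3, adjusted p = 0.051, and LOC132657733, 0.0706), in exposed lambs 1; DESeq2 gave 54 and voom with sample weights 64 in controls, and the cause was not tested. Leaving out 1 lamb gave 10 to 23 genes for sex in controls, 12 to 21 in exposed lambs and 0 for exposure and the interaction. The numbers of lists called for exposure (10 in females, 14 in males, 13 over both sexes) became 0 in each with an estimated correlation, with fry and with permutation of list means, tests that take account of how the members of a list vary together. Without biosolids male 8778 and control female 8263 they were 5, 8 and 8, and with 2 surrogate variables 7 over both sexes. Leaving out 1 lamb gave 5 to 12 lists in females, with 5 without control female 8263, 7 to 19 in males, with 7 without biosolids male 8735 and 8 without 8778, and 10 to 14 over both sexes. The correlation of female and male effects (0.0422) was -0.0309 with 2 surrogate variables and 0.00203 without the 2 libraries; the cause was not tested. LOC121818987, called higher in exposed males than females, was at -0.62 with DESeq2 and -0.56 without the 2 libraries, which for the latter follows from leaving out lamb 8778 and for DESeq2 has a cause that was not tested. Of 120 log2 fold changes of named genes, the sign changed for 7 with 2 surrogate variables, 5 with voom, 5 without the 2 libraries, 3 with DESeq2 and 1 with RLE; calls were lost for 10, 7, 7, 5 and 0 of them, for 4 of 93 with the 1 CPM filter and for 2 without a filter, and DESeq2 added 7. LCN2 and NCAM1 in controls are among those lost with 2 surrogate variables and without the 2 libraries. Fits without the 2 libraries and permutation of list means were chosen after seeing the data. Depth limits biosolids male 8778 most, with 2.34 M counts outside ribosomal RNA.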

Other observations

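In control males the nuclear genes of oxidative phosphorylation had a lower mean than in control females for 51 of 59 members, with a median log2 fold change of -0.45, and 19 passed when adjusted over the list alone against 0 over all genes. ATP5PF, at -0.63 ± 0.16 (SE), and ATP5MC3, at -0.48 ± 0.14, both subunits of ATP synthase, had the smallest p. The cytosolic ribosomal proteins were lower on average for 73 of 74, with a median of -0.47, led by RPS4X at -0.52 ± 0.18 and RPL30 at -0.54 ± 0.21. Both lists had an adjusted p of 0.511 with an estimated correlation, and the exact two-sided permutation test of the list means gave adjusted p of 0.102 and 0.234. In exposed males all 32 interferon-stimulated genes had a lower mean than in control males, with a median of -0.54 (adjusted p = 0.66 with an estimated correlation). The list means differed by -0.49 (exact permutation p = 0.181, adjusted p = 0.611), and by -0.26 without control male 8428, which had the highest list mean of the males at 5.96 log2 CPM. Without biosolids male 8778, the highest of the exposed males at 5.06 log2 CPM, they differed by -0.64 (exact permutation p = 0.0746, adjusted p = 0.535). The sex tests of lists, the row of KEF53_p02 and the length check were chosen after the data were seen.

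Other splits of the lambs were refitted to see whether other groupings of the animals give as much, with 100 splits for each result, the real one included. For exposure in females the 652 genes at an unadjusted p under 0.05 were matched or exceeded in 65 splits, with up to 5151 genes; in males the 970 in 25 splits, with up to 3609; over both sexes the 768 in 48 splits, with up to 5086; and for the interaction the 648 in 64 splits, with up to 4160. As the real splits called 0 genes, all 100 splits gave as many, and the highest others called 750, 1 and 1691 genes for females, males and both sexes and 1 for the interaction. The highest ones point to a structure of the samples that does not follow exposure. The lists called with the preset correlation (10, 14 and 13) were matched or exceeded in 71, 38 and 43 splits, with up to 24, 26 and 24 lists, so that chance is not excluded for any of them. The correlation of 0.0422 between female and male effects was as far from 0 in 70 splits, the farthest being 0.3.

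For sex in exposed lambs, only the real split called as many as 17 genes (1 of 100; highest other 9). Of these, 9 are Y-linked and are called because the real split is the split by sex, and 6 come from biosolids male 8778, so the count says nothing about chance for other genes. For sex in controls, 5 of the 100 splits called 15 or more genes, with up to 1104, and 8 had at least the 3370 genes at an unadjusted p under 0.05, with up to 5232; in exposed lambs 39 splits had at least 865, with up to 3341. Chance is therefore not excluded for the breadth of the difference between control males and females, although its 9 Y-linked genes check the labels. Across genes the log2 fold change of sex in controls had a Spearman correlation of 0.119 with gene length, as far from 0 in 43 of 100 splits.

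KEF53_p02, a gene of the mitochondrial genome, had 1154 counts in biosolids female 8775 and 756 in control male 8425, and at most 36 in any of the other libraries.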
